A study of Zea mays with 8 samples.

How the data were processed

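RNA-seq was done on maize inbred B73 grown in a greenhouse, in 8 libraries: ovary and basal leaf meristem, well watered or under drought, with 2 libraries in each of the 4 groups. The libraries were made from polyadenylated RNA, per the labels. Groups and replicate numbers were taken from the sample titles. The series description counts 1 biological replicate for each condition while the sample labels give 2; each table holds 1 column per library, so each was used as a replicate. Per the submitters' processing notes CASAVA 1.8, TopHat 1.2.0 and Cufflinks 1.0.2 were used; their roles and settings are not given in the sources used here. The deposited values are FPKM, made by the authors, in 1 table per tissue. Whether the authors scaled the libraries further, which genome build and annotation they used, and by which rule a gene was listed are not given in the sources used here, so no coordinates are printed. Read counts are not given in the sources used here, so the depth per library is unknown, as is the counting error of each value.

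Gene IDs were matched to symbols through the synonyms of the RefSeq annotation of the B73 genome. Of 26380 ovary IDs, 16218 matched a RefSeq gene, 449 matched more than 1, and 2223 had a symbol other than a LOC, clone or marker name. Of 25873 leaf IDs these numbers were 16109, 444 and 2199, and 23586 IDs were in both tables. The reference gives no product names, so lists were matched on symbols alone.

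Each tissue was analysed within its own table in R 4.3.3 with limma 3.58.1 (lmFit, eBayes with trend) on log2(FPKM + 1), over genes with a mean of at least 1 FPKM in that table. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Each tissue fit has 2 residual degrees of freedom, to which limma added a prior of 3.74 in the ovary and 2.42 in the leaf. Values after ± are standard errors of the limma fit. The difference between tissues was tested over all 8 libraries as the ovary change minus the leaf change, for genes with a mean of at least 1 FPKM in both tables. Calls shared by both tissues were compared with independent lists by a two-sided Fisher's exact test across genes. Genes at exactly 0 in both libraries of a condition (641 tested in the ovary, 202 in the leaf) are given in the tissue results by their library values, with no fold. Fitted differences between tissues for such genes are given as values that depend on the pseudocount. Equal zeros add no spread, so the limma p-values of such genes rest on the other libraries and the prior. Where a zero is a missing estimate, these p-values measure nothing. The medians of lists called within a tissue are given also without such genes where that changes them.

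There were 34 gene lists, and camera (limma, preset correlation 0.01) tested each list with at least 5 members measured, with adjustment over lists and again with an estimated correlation. The lists were ABA synthesis and signalling, type 2C protein phosphatases, dehydrins and LEA, aquaporins, antioxidant enzymes, heat shock proteins, NAC, WRKY, DREB and ERF, HD-ZIP and bZIP factors, auxin, gibberellin, ethylene, jasmonate and lipoxygenases, phospholipid and inositol signalling, starch, sucrose and hexose, trehalose, raffinose and polyols, proline, cyclins and their kinases, DNA replication, histones, kinesins and tubulins, expansins with xyloglucan and cellulose enzymes, ribosomal proteins, photosynthesis, cell death with proteases and autophagy, and metallothioneins with lipid transfer proteins and protease inhibitors. The other lists were markers of floral MADS-box, KNOX and vegetative meristem, lignified vascular, pollen and anther, and endosperm storage genes. Lists overlap: all tested type 2C phosphatases are in the ABA list, and the ethylene and DREB and ERF lists share 17 members in the ovary and 22 in the leaf. Comparisons, tests, lists, candidate symbols and the rule for named genes were fixed before the data were examined.

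The rule names, in each tissue, the 5 rising and 5 falling genes with the largest log2 change among called genes with a symbol whose drought libraries both lie beyond both controls. It also names the 3 largest changes of each list with at least 3 called members, of which the text may leave some out, and all measured genes among 30 candidate symbols. In the difference between tissues it names the 5 largest each way. Chosen after seeing the data were the same choices among genes not at 0, which in the tissue difference also need a symbol, the genes named as shared by both tissues, AC198871.3_FG002, AC195320.3_FG003, and the genes and lists of the other observations.

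Alternatives tried were pseudocounts of 0.1 and 0.01 FPKM, no filter beyond a mean above 0, a mean of at least 5 FPKM, quantile normalization, upper quartile scaling, eBayes without trend, a 2-fold minimum, a joint fit of all 8 libraries, the replicate number as a block, and each library left out in turn. With a library left out, the lone library of its condition is assumed to vary like the other pair. Added after seeing the data were fits without genes at 0 in both libraries of a condition, lists without members whose symbol names another class of gene, a block with crossed replicate numbers in the leaf, and, for the calls shared by both tissues, each library left out and the replicate block. With 2 libraries per group, regroupings of the samples and an outlier test were not run.

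The procedure was tested on simulated data with independent genes, each with the spread that limma fitted to it in these libraries, where 100 genes were changed 2-fold and 100 changed 4-fold. In the ovary limma found 56 and 99 of them, with 26 false calls among 181, and in the leaf 36 and 90, with 16 false calls among 142. In both tissues the share of false calls was above the adjusted p threshold used for a call. Within a tissue, the share of false calls can thus be larger than that threshold states. For the tissue difference, simulated with the same spread for every gene, limma found 197 of 200 genes changed 4-fold, with 11 false calls. Camera called the list that was moved with the preset correlation in both tissues, but not with an estimated correlation (adjusted p = 0.22 and 0.189), and called 0 of 30 lists that were not moved. Because the simulated genes were independent, this cannot tell how often camera calls lists of correlated genes falsely.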

Results

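Transcript levels were measured by RNA sequencing of polyadenylated RNA in the maize inbred line B73, in the ovary and in the basal meristem of the 3 youngest leaves, 24 hours after hand pollination. The series description names the control ovary samples as ovaries/cob and the drought samples as ovary tissue. The share of cob tissue in either is not known. Plants were well watered, or irrigation was withheld for 2 to 3 days before pollination. Each tissue and watering condition has 2 libraries, 8 in all, which the labels call biological replicates. The labels do not say whether they came from separate plants, so the p-values measure the spread between these libraries. Values are FPKM, fragments scaled to the length of the gene model and to the mapped fragments of the library, for 26380 genes in the ovary and 25873 in the leaf. Read counts are not used here, so the depth of each library is unknown and no interval for counting error can be given. The FPKM of a library summed to between 783683 and 843595 in the leaf. In the ovary the sums were 706954 in control 1, 661161 in drought 1 and 710996 in drought 2. Ovary control 2 summed to 9212840, because AC198871.3_FG002 and AC195320.3_FG003 stood at 7567260 and 912126 FPKM in that library only, and to 733453 without both genes. Across genes, which are not independent replicates, the Pearson correlation of log2(FPKM + 1) was 0.964 between the ovary controls, 0.981 between the ovary drought libraries and 0.646 to 0.712 between conditions. In the leaf it was 0.953 between the controls, 0.985 between the drought libraries and 0.873 to 0.930 between conditions. Leaf control 2 was the control farther from drought, at 0.894 and 0.873, against 0.930 and 0.918 for leaf control 1.

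The ovary comparison asked which transcripts drought changes in the reproductive organ at the time of fertilization. Transcripts of a dehydrin gene, a metallothionein gene and many of the tested type 2C protein phosphatases and NAC factors were higher in drought-stressed ovaries. Those of most tested histones, kinesins and tubulins, expansins and cellulose synthases and ribosomal proteins were lower. The dehydrin gene dhn1 (GRMZM2G079440), also known as rab17 and induced by abscisic acid, rose from 8.81 and 22.3 FPKM in the control libraries to 2559 and 2094 FPKM under drought, a log2 change of 7.26 ± 0.41 (SE, n = 2 per condition, limma adjusted p = 0.000125). The metallothionein gene mtl2 (GRMZM2G402564) rose from 2.62 and 4.31 to 330.5 and 350.5 FPKM (log2 change 6.28 ± 0.22, limma adjusted p = 4.63e-05). The beta-expansin gene expB6 (GRMZM2G176595), whose product loosens cell walls, fell from 149 and 273 to 0.514 and 1.33 FPKM (log2 change -6.75 ± 0.35, limma adjusted p = 0.0001). The chalcone isomerase gene chi1 (GRMZM2G155329), of flavonoid synthesis, fell from 484 and 989 to 4.98 and 8.45 FPKM (log2 change -6.53 ± 0.39, limma adjusted p = 0.000148).

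Several of the largest changes were in genes listed at exactly 0 in both libraries of a condition, for which no fold is given. Atg8b (GRMZM2G419694), of autophagy, was listed at 0 in both controls and at 107 and 134 FPKM under drought. The homocysteine methyltransferase gene HMT-3 (GRMZM2G152470) was at 0 in both controls and at 109 and 86.0 FPKM under drought, and hppd1 (GRMZM2G088396), of tocopherol synthesis, at 0 and then at 65.9 and 136 FPKM. Conversely, A1 (GRMZM2G026930), the dihydroflavonol reductase of anthocyanin synthesis, stood at 801 and 1319 FPKM in the controls and was listed at 0 in both drought libraries. The translation factor gene eif5a (GRMZM2G113696, controls 446 and 487 FPKM), the 14-3-3 gene grf2 (GRMZM2G078641, 362 and 294), the chalcone synthase gene c2 (GRMZM2G422750, 222 and 357) and sm2 (GRMZM2G180283, 162 and 295), of silk flavone synthesis, were also listed at 0 in both drought libraries. All 8 passed limma, with adjusted p between 1.72e-05 and 0.000107. Equal zeros show no spread, so these p-values can be too small. Among genes not at 0, a choice made after seeing the data, the other large rises were in the LEA gene mlg3 (GRMZM2G096475, log2 change 5.74), sat1 (GRMZM2G069203, 5.08) and the zeatin glucosyltransferase gene ciszog1 (GRMZM2G168474, 4.95). The other large falls were in hsbp1 (GRMZM2G085924, log2 change -6.22), a heat shock factor binding protein, in CER1 (GRMZM2G066578, -6.08), of cuticular wax synthesis, and in CGTb (GRMZM2G383404, -6.08).

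Camera called the lists of growth and division as falling, though none with an estimated correlation. Of the 25 expansin, xyloglucan endotransglucosylase and cellulose synthase genes tested, 23 fell and none rose, the same numbers as adjusted over the list alone, with a median log2 change of -2.54 (-2.52 without genes at 0). The camera test of the list gave an adjusted p = 6.08e-09 and an adjusted p = 0.561 with an estimated correlation. After expB6, the alpha-expansin expa1 (GRMZM2G339122) fell by 5.50 and expB4 (GRMZM2G154178) by 5.35 on the log2 scale. The genes cesa2 (GRMZM2G027723, controls 130 and 114 FPKM) and expA3 (GRMZM2G074585, 58.3 and 107) were listed at 0 in both drought libraries. Of 24 kinesin and tubulin genes, 20 fell and 1 rose, also when adjusted over the list alone (median -2.20, camera adjusted p = 1.1e-06, and adjusted p = 0.561 with an estimated correlation). The tubulin genes tub6 (GRMZM2G071790), tub4 (GRMZM2G066191) and tub5 (GRMZM2G133802) fell by 4.49, 3.87 and 3.61. Of 12 histone genes, 11 fell, or 12 adjusted over the list alone (median -3.22, camera adjusted p = 3.08e-05, and adjusted p = 0.561 with an estimated correlation). The largest falls were in H4C13 (GRMZM2G084195, -5.41), H3C2 (GRMZM2G401581, -4.54) and his2a1 (GRMZM2G305046, -4.26). Of 8 DNA replication genes, 4 fell, also when adjusted over the list alone (median -1.19, camera adjusted p = 0.0199, and adjusted p = 0.573 with an estimated correlation). They include the sliding clamp gene pcna2 (GRMZM2G108712, -4.07) and the helicase subunits MCM6 (GRMZM2G021069, -2.94) and MCM7 (GRMZM2G065205, -2.73). Of 21 genes matched as cyclins and their kinases, 14 fell and 3 rose, also when adjusted over the list alone (median -1.38, or -1.22 without genes at 0, camera adjusted p = 0.00947, and adjusted p = 0.574 with an estimated correlation). That list holds 7 kinesin-related genes through their krp symbols. Without them 8 of 14 fell with a median of -1.09 and a camera adjusted p of 0.203, and among genes at a mean of 5 FPKM or more the median was -1.07 and the camera adjusted p 0.19. The largest falls of the list were in csh9 (GRMZM2G034647), a cyclin gene at 10.04 and 5.89 FPKM in the controls and listed at 0 in both drought libraries, in the retinoblastoma-related rbr3 (GRMZM2G033828, -2.57) and in kin11 (GRMZM2G436981, -2.57), which is 1 of the kinesin-related genes.

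Ribosomal protein genes fell in 25 of 30 cases and rose in 1, also when adjusted over the list alone, with a median log2 change of -1.48 (-1.5 without genes at 0, camera adjusted p = 4.55e-06, and adjusted p = 0.561 with an estimated correlation). RPS27A (GRMZM2G431821) fell by 2.24 and rps28 (GRMZM2G030293) by 2.13. The exception, RPL10 (GRMZM2G087233), was listed at 0 in both controls and at 46.0 and 59.6 FPKM under drought. Of 9 markers of lignified vascular tissue, 8 fell and 1 rose, also when adjusted over the list alone (median -2.69, or -2.53 without genes at 0, camera adjusted p = 0.0032, and adjusted p = 0.561 with an estimated correlation). They include pal3 (GRMZM2G074604, -4.43), phenylalanine ammonia lyase, the lignin gene BM1 (GRMZM5G844562, -3.76) and the laccase lac4 (GRMZM2G072780), at 6.48 and 9.15 FPKM in the controls and listed at 0 in both drought libraries. Of 29 photosynthesis genes, 18 fell and 2 rose, or 20 and 3 adjusted over the list alone (median -0.98, or -0.91 without genes at 0, camera adjusted p = 0.00271, and adjusted p = 0.574 with an estimated correlation). The light-harvesting gene lhcb6 (GRMZM2G092427) fell by 4.10 and the Rubisco small subunit rbcS (GRMZM2G113033) by 3.32. Another, lhcb3 (GRMZM2G155216, controls 85.8 and 178 FPKM), was listed at 0 in both drought libraries. Starch genes fell in 11 of 16 cases and none rose, also when adjusted over the list alone (median -1.47, camera adjusted p = 0.00286, and adjusted p = 0.582 with an estimated correlation). Among them, the granule-bound starch synthase GBSSIIa (GRMZM2G008263) fell by 3.20. The log2 change of the ADP-glucose pyrophosphorylase subunit AGPLS3 (GRMZM2G144002) was -2.53. A further member by its symbol, ss2 (GRMZM2G152908, -3.05), is the sucrose synthase gene sus1 and no starch synthase.

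Camera called the lists of abscisic acid, type 2C phosphatases, NAC factors, cell death and autophagy, and KNOX and vegetative meristem markers as rising, though none with an estimated correlation. Of 41 genes of abscisic acid synthesis and signalling, 21 rose and 8 fell, or 23 and 9 adjusted over the list alone (median 0.66, camera adjusted p = 0.00291, and adjusted p = 0.574 with an estimated correlation). That list holds all 23 tested type 2C protein phosphatases, which act in abscisic acid signalling. Of these, 14 rose and 3 fell, or 15 and 3 adjusted over the list alone (median 0.86, camera adjusted p = 0.00221, and adjusted p = 0.561 with an estimated correlation). PP2C4 (GRMZM2G177386) rose from 38.2 and 36.6 to 340 and 361 FPKM (log2 change 3.19 ± 0.14), PP2C11 (GRMZM2G308615) by 2.85 and PP2C16 (GRMZM2G082487) by 2.81. Of the other 18 genes of the abscisic acid list, 7 rose and 5 fell. Of 21 NAC transcription factors, 11 rose and 3 fell, or 13 and 3 adjusted over the list alone (median 0.67, camera adjusted p = 0.00271, and adjusted p = 0.561 with an estimated correlation). The symbol NAC1 belongs to 3 gene IDs, GRMZM2G347043, which rose by 3.96, and GRMZM2G336533 and GRMZM2G018553, which both match 1 reference gene and rose by 3.35 and 3.34. Of 25 genes of cell death and autophagy, 12 rose and none fell, also when adjusted over the list alone (median 0.70, or 0.66 without genes at 0 and 0.45 without control 2, camera adjusted p = 0.000901, and adjusted p = 0.582 with an estimated correlation). After Atg8b they were led by the ribosome-inactivating protein gene rip2 (GRMZM2G119705, 4.54), the autophagy gene Atg7 (GRMZM2G005304, 2.34) and lls1 (GRMZM2G339563, 2.14), of chlorophyll breakdown. Of 17 markers of vegetative meristems and KNOX genes, 10 rose and 2 fell, also when adjusted over the list alone (median 0.92, camera adjusted p = 0.0179, and adjusted p = 0.561 with an estimated correlation). The homeobox genes gnarley1 (GRMZM2G452178, 3.04) and kn1 (GRMZM2G017087, 2.21) and the leaf patterning gene lg2 (GRMZM2G060216, 2.12) rose most. The camera adjusted p of this list was 0.05002 without ovary drought 1 and 0.0591 among genes at a mean of 5 FPKM or more. With a library left out, limma no longer called kn1 (adjusted p = 0.0508 without control 2, 0.075 without drought 1 and 0.0565 without drought 2), gnarley1 (adjusted p = 0.0601 without drought 1 and 0.0553 without drought 2), rip2 (0.0601 without drought 2) or Atg7 (0.0523 without drought 2).

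The camera test called none of the other 17 lists tested in the ovary. In sucrose and hexose metabolism 2 of 11 rose and 6 fell (camera adjusted p = 0.316). In trehalose metabolism 6 of 12 rose and 2 fell (camera adjusted p = 0.186). The fructokinase gene frk2 (GRMZM2G051677) fell by 2.96, and in the trehalose list TPS9 (GRMZM2G122231) rose by 2.95 and EDS (GRMZM2G010356), a terpene synthase gene matched through its synonym TPS17, fell by 3.52. TPS3 (GRMZM2G118462) was listed at 0 in both controls and at 50.6 and 69.2 FPKM under drought. In the dehydrin and LEA list 6 of 15 rose and 3 fell (median 0.44, camera adjusted p = 0.132). Of these 15, 9 were matched through symbols of embryo loci or small GTPases, and of the other 6 genes 4 rose and 1 fell (median 2.11), also without a call by camera. For aquaporins 2 of 20 rose and 11 fell, with a log2 change of -2.94 for pip2c (GRMZM2G081192). For auxin 5 of 33 rose and 15 fell, with AUX10 (GRMZM2G057067) rising by 3.40 (limma adjusted p = 0.0603 without ovary drought 2) and a log2 change of -2.99 for AUX17 (GRMZM2G079957). For heat shock proteins 4 of 20 rose and 10 fell, with hsp82 (GRMZM5G833699) rising by 3.20. That list shares 3 genes with the aquaporin list, and of its 18 genes without members of another class 4 rose and 9 fell. For ethylene 5 of 25 rose and 11 fell, for DREB and ERF factors 7 of 21 rose and 8 fell. For jasmonate and lipoxygenases 7 of 38 rose and 11 fell, with lox1 (GRMZM2G156861) falling by 2.95. For HD-ZIP and bZIP factors 17 of 44 rose and 10 fell, with bZIP89 (GRMZM2G158313) falling by 4.30 and rld1 (GRMZM2G109987) listed at 0 in both controls and at 35.3 and 37.8 FPKM under drought. For WRKY factors 7 of 17 rose and 4 fell, for antioxidant enzymes 1 of 10 rose and 3 fell, for gibberellin 1 of 6 rose and 1 fell. For metallothioneins, lipid transfer proteins and protease inhibitors 1 of 8 rose and 3 fell, with LTP3 (GRMZM2G126397) falling by 4.24. Among tissue markers, 8 of 28 floral MADS-box genes rose and 11 fell, with MADS18 (GRMZM5G805387) falling by 2.46. Of the others, 1 of 6 pollen markers rose and 4 fell, and 1 of 5 endosperm storage markers rose. Adjusted over the list alone, 3 aquaporins rose and 12 fell, 7 dehydrin and LEA genes rose, 8 DREB and ERF factors rose. On the same basis 6 ethylene genes rose and 12 fell, 18 HD-ZIP and bZIP factors rose and 4 genes of the metallothionein list fell, with no other change among these lists. Camera adjusted p of these 17 lists lay between 0.075 and 0.956. The median (-0.07, or -0.04 without genes at 0) and mean (-0.11) of the DREB and ERF list were of the other sign than its camera direction, and the mean of the jasmonate list (-0.06) likewise. The trehalose median was 0.85, or -0.17 without genes at 0, or 1.87 without 1 other member whose symbol names a terpene synthase. Lists with fewer than 5 members tested in the ovary had no camera test. All 3 raffinose and polyol genes rose, with the galactinol synthase gene gols2 (GRMZM5G872256) rising by 3.36, sip1 (GRMZM2G374971) by 1.38 and mips2 (GRMZM2G004528) by 0.89. Limma did not call sip1 at a pseudocount of 0.1 FPKM (adjusted p = 0.0527) or without control 1 (0.25), control 2 (0.273) or drought 2 (0.0808), where its log2 change was 0.64, against 2.11 without drought 1. It did not call mips2 without control 1 (0.12), control 2 (0.165) or drought 1 (0.092). Both phospholipid signalling genes fell, and 1 of 3 genes matched as proline metabolism through the symbols pdh1 and pdh2, which are other dehydrogenases, fell.

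Of the genes chosen as drought or ovary candidates, 21 were measured in the ovary, of which 5 rose, 11 fell and 5 did not pass limma. The sucrose synthase genes moved apart: sh1 (GRMZM2G089713) rose from 263 and 239 to 765 and 947 FPKM (log2 change 1.76 ± 0.19, limma adjusted p = 0.000978) and sus2 (GRMZM2G318780) by 1.501, while ss2 (sus1) fell from 517 and 387 to 58.7 and 48.0 FPKM (log2 change -3.05 ± 0.21, limma adjusted p = 0.000219). The invertase genes mn1 (GRMZM2G119689), a cell wall form, ivr2 (GRMZM2G089836), a vacuolar form, and invertase1 (GRMZM2G394450), known as ivr1, had log2 changes of -1.59, -1.17 and -2.18, while incw1 (GRMZM2G139300), another cell wall form, did not pass limma (0.13, adjusted p = 0.829). The catalase gene cat1 (GRMZM2G088212) rose by 1.44. The small subunit gene of ADP-glucose pyrophosphorylase bt2 (GRMZM2G068506), pcna1 (GRMZM2G030523), the DELLA gene D8 (GRMZM2G144744), the MADS-box gene MADS37 (GRMZM2G052890), known as zag1, the Rubisco gene rbcs1 (GRMZM2G098520) and Pep1 (GRMZM5G899080) fell by 1.56, 1.98, 1.08, 0.66, 2.03 and 1.32. Log2 changes were 0.09 for vp14 (GRMZM2G014392), of abscisic acid synthesis, -0.41 for sod4 (GRMZM2G169890), 0.40 for d9 (GRMZM2G024973) and 0.25 for hsp101 (GRMZM2G360681), with limma adjusted p = 0.787, 0.0741, 0.185 and 0.424. D8 and MADS37 were called only with all 4 libraries present (adjusted p between 0.0575 and 0.113, and between 0.0676 and 0.141, without control 1, control 2, drought 1 or drought 2). The limma calls of mn1 (0.0557 without drought 1, 0.0663 without drought 2), ivr2 (0.116 without control 2, 0.11 without drought 1, 0.19 without drought 2), sus2 (0.0816 without control 1, 0.0879 without control 2), bt2 (0.0504 without control 1, 0.0511 without control 2), rbcs1 (0.0712 without drought 1, 0.0795 without drought 2) and Pep1 (0.0604 without control 2) also ended with a library left out.

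In all, limma called 12618 of the 23770 ovary genes tested (53.1%) at an adjusted p under 0.05, 5614 rising and 7004 falling, and 14161 at an unadjusted p under 0.05. After quantile normalization it called 12863, 6657 rising and 6206 falling, so which direction was the more frequent depends on the scaling. At least 2-fold changes made up 3254 of the rising and 4668 of the falling calls. Of the calls, 637 were of genes listed at 0 in both libraries of a condition, 283 rising and 354 falling. Fewer genes passed with fewer libraries: 8595 without control 1, 7165 without control 2, 7064 without drought 1 and 5800 without drought 2. Both drought libraries lay on the same side of both controls in every gene named here as rising or falling. The median log2 change of all tested genes was -0.05, and 0.07 after quantile normalization, a shift of 0.11. Relative to that median, the lists called as rising had medians of 0.69 to 1.05 and those called as falling -3.24 to -1.06, and no called list changed direction.

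**Figure D1:**
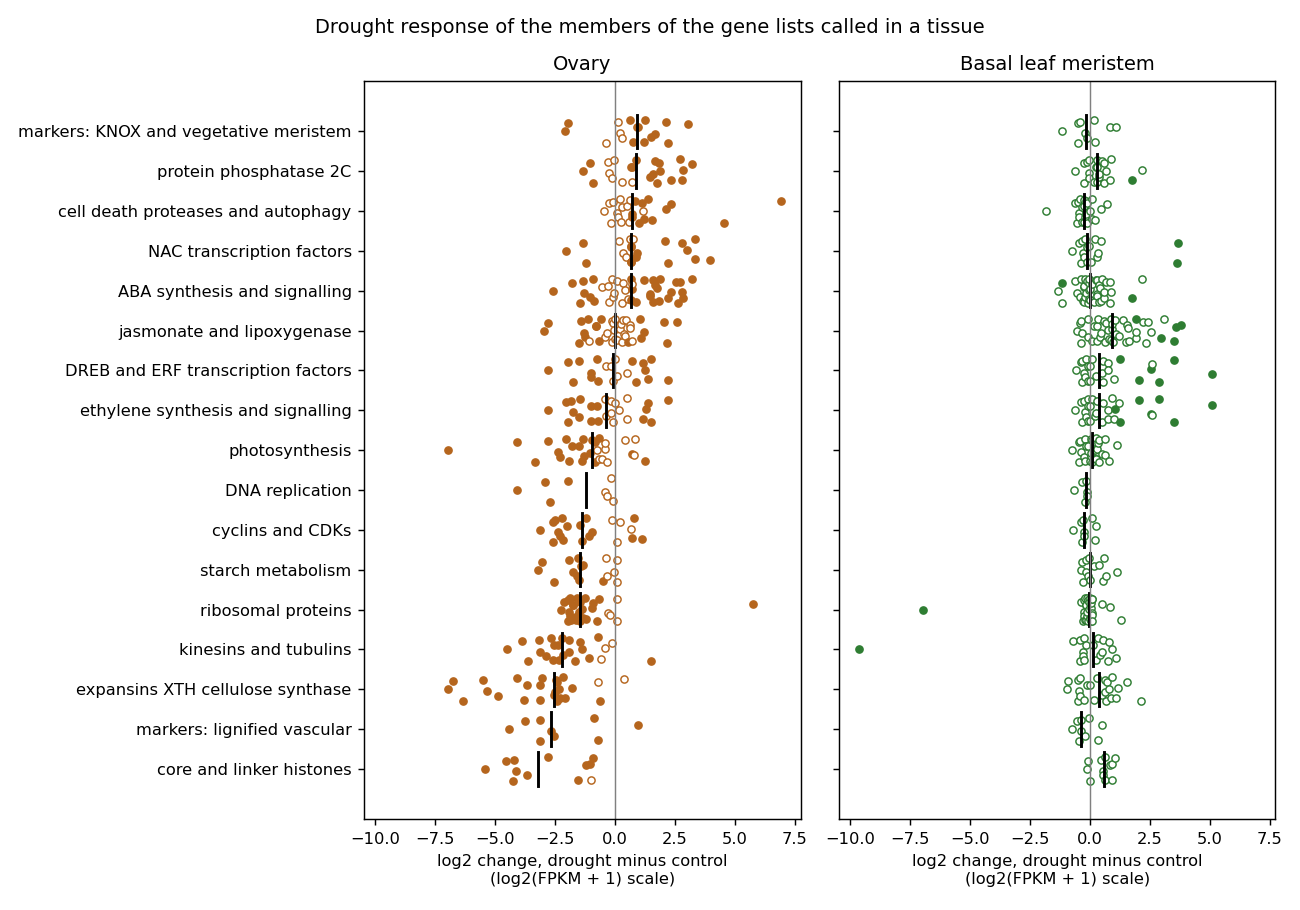
Log2 change with drought (log2(FPKM + 1) scale, drought minus control) of each tested member of the gene lists that camera called in either tissue, in the ovary (left) and the basal leaf meristem (right). Each point is a gene, filled where limma's adjusted p was under 0.05, and the black bar is the list's median, which in the ovary runs from -3.22 for histones to 0.92 for KNOX and vegetative meristem markers.

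The leaf comparison asked which transcripts drought changes in the growing base of young leaves. Camera called the lists of jasmonate, ethylene, DREB and ERF factors and type 2C phosphatases as rising, though none with an estimated correlation, and most members of each list did not pass limma. The bHLH factor genes bHLH108 (GRMZM2G119823) and bHLH116 (GRMZM2G042895) rose from 2.14 and 0.962 to 90.9 and 164 FPKM (log2 change 5.63 ± 0.38 SE, n = 2 per condition, limma adjusted p = 0.00723) and from 43.7 and 20.9 to 1052 and 1453 FPKM (log2 change 5.30 ± 0.40, limma adjusted p = 0.00972). Of 44 genes of jasmonate synthesis and signalling and lipoxygenases, 5 rose and none fell, and 21 rose adjusted over the list alone (median log2 change 0.92, or 0.57 without leaf control 2, camera adjusted p = 1.16e-09, and adjusted p = 0.968 with an estimated correlation). All 5 are TIFY genes, the family of jasmonate signalling repressors, with TIFY9 (GRMZM2G145412) rising by 3.80, TIFY20 (GRMZM2G173596) by 3.58 and TIFY28 (GRMZM2G036351) by 3.53. With the replicate block, limma did not call TIFY20 or TIFY28 (adjusted p = 0.0748 and 0.0816). Without leaf control 2, limma called none of these 3 (adjusted p = 0.0718, 0.0754 and 0.0809), and without leaf drought 1 or leaf drought 2 it called no leaf gene (2526 and 1800 at an unadjusted p under 0.05). In leaf control 2, 40 of the 44 jasmonate genes lay below leaf control 1, with a median log2 difference of -0.49.

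Of 30 ethylene genes, 7 rose, 12 adjusted over the list alone and 4 of 28 in the fit without genes at 0 (median 0.40, or 0.28 without genes at 0, camera adjusted p = 4.34e-05, and adjusted p = 0.725 with an estimated correlation). The list shares 22 members with the 26 DREB and ERF factors, of which 6 rose, 9 adjusted over the list alone and 4 of 24 in the fit without genes at 0 (median 0.37, or 0.18 without genes at 0, camera adjusted p = 0.000884, and adjusted p = 0.725 with an estimated correlation). Without the shared members, 1 of 8 ethylene genes rose. DBP4 (GRMZM2G380377) rose by 3.50, EREB27 (GRMZM2G084264) by 2.57 and EREB65 (GRMZM2G124011) by 2.06. EREB171 (GRMZM2G013657) and EREB139 (GRMZM2G103085) were listed at 0 in both controls and stood at 36.9 and 29.6 FPKM and at 3.92 and 9.80 FPKM under drought. Limma did not call EREB65 without leaf control 2 (adjusted p = 0.075) or EREB139 without leaf control 1 (0.0679), without leaf control 2 (0.146) or with the replicate block (0.0767). Of 22 type 2C protein phosphatases, 1 rose, 4 adjusted over the list alone and 0 in the fit without genes at 0 (median 0.31, camera adjusted p = 0.00416, and adjusted p = 0.761 with an estimated correlation). Their median in leaf control 2 lay at -0.27 relative to leaf control 1. Of 16 trehalose genes, 3 rose, 5 adjusted over the list alone and 2 in the fit without genes at 0: TPS9 (1.95), TPS2 (GRMZM2G123277, 1.89) and TPS7 (GRMZM2G019183, 1.26), which limma did not call without leaf control 2 (adjusted p = 0.0739). With the replicate block it called neither TPS9 (adjusted p = 0.0817) nor TPS7 (0.121). The camera adjusted p of that list was 0.0584, and 0.0033 without its 4 members whose symbols name terpene synthases.

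Among single genes with a symbol, the largest rises included 3 genes listed at 0 in both controls, AGA1 (GRMZM2G340656, 222 and 264 FPKM under drought), the auxin-binding protein gene abp1 (GRMZM2G116204, 156 and 168) and Ots1c (GRMZM2G142553, 40.8 and 38.3). The 5 largest falls among genes with a symbol were in genes listed at 0 in both drought libraries: the kinesin gene kin1 (GRMZM2G158394, controls 2163 and 287 FPKM), arpp1a (GRMZM2G032315, 133 and 116), an acidic ribosomal protein, pdh2 (GRMZM2G127798, 113 and 87.7), a phosphogluconate dehydrogenase, the splicing factor gene RS2Z37B (GRMZM2G099317, 42.4 and 47.9) and bZIP83 (GRMZM2G000171, 28.1 and 31.8). Limma adjusted p of these 8 genes lay between 0.000348 and 0.0216, and can be too small because equal zeros show no spread. Among genes not at 0, a choice made after seeing the data, LOB15 (GRMZM2G060544) and NAC1 (GRMZM2G336533) rose by 4.83 and 3.69. The falls were in HSP90-1 (GRMZM2G024668), from 106 and 75.9 to 15.7 and 11.01 FPKM (log2 change -2.67 ± 0.25, limma adjusted p = 0.0169), the aquaporin tip4b (GRMZM2G108273, -2.26), Dwarf1 (GRMZM2G036340, -1.95), sat2 (GRMZM2G013430, -1.86) and MYBE1 (GRMZM2G145041, -1.83). Of 43 HD-ZIP and bZIP factors, 1 rose and 3 fell (0 and 1 in the fit without genes at 0), with bZIP76 (GRMZM2G134863) rising by 1.49 and bZIP9 (GRMZM2G092137) and HB127 (GRMZM2G119999) falling by 1.31 and 1.27 (camera adjusted p = 0.35). Without leaf control 2, limma did not call tip4b, Dwarf1, sat2, bZIP76, bZIP9 or HB127 (adjusted p = 0.0896, 0.0852, 0.0774, 0.116, 0.0714 and 0.102), nor Dwarf1 without leaf control 1 (0.052). With the replicate block it did not call NAC1, tip4b, Dwarf1, sat2, bZIP76, bZIP9 or HB127 (adjusted p = 0.0875, 0.0533, 0.0687, 0.0994, 0.106, 0.1 and 0.108), nor NAC1 and Dwarf1 at a pseudocount of 0.1 FPKM (0.0696 and 0.124). All 21 measured candidate genes missed limma's threshold: dhn1 stood at 17.2 and 4.98 FPKM in the controls and 47.4 and 129 FPKM under drought (log2 change 2.93 ± 0.73, limma adjusted p = 0.141). The other candidates with log2 changes beyond 1 were ivr2 (2.46, limma adjusted p = 0.291), hsp101 (1.27; 0.175) and the catalase gene cat2 (GRMZM2G090568, -1.198; 0.212). Without leaf control 1, limma called ivr2 (log2 change 4.13; adjusted p = 0.0337) and cat2 (-1.81; 0.0203). Log2 changes of vp14, incw1, invertase1, sh1, ss2, sus2, sh2 (GRMZM2G429899), bt2, pcna1, pcna2, cat1, sod4, D8, d9, rbcs1, pep1 (GRMZM2G083841) and Pep1 lay between -0.65 and 0.90, with limma adjusted p between 0.162 and 0.974.

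Among the other lists, camera adjusted p lay between 0.0771 for cell death and autophagy, where none of 23 genes passed limma, and 0.971. In the ABA list 1 of 41 rose and 1 fell, in the auxin list 2 of 38 rose. In the NAC list 2 of 17 rose, and 1 rose in each of the lists of dehydrins and LEA (14 tested, 5 of them without the embryo loci and small GTPases), gibberellin (7) and metallothioneins, lipid transfer proteins and protease inhibitors (7). Aquaporins fell in 2 of 19 cases, and 1 fell among heat shock proteins (18 tested), kinesins and tubulins (19) and ribosomal proteins (32). In the fit without genes at 0, no gene rose in the ABA, auxin, NAC or metallothionein lists and none fell among kinesins and tubulins or ribosomal proteins. No member passed limma among 10 antioxidant enzymes, 12 histones, 9 cyclins and their kinases, 6 DNA replication genes, 24 expansins and cellulose synthases, 30 photosynthesis genes, 14 starch genes, 10 sucrose and hexose genes, 19 WRKY factors or the markers of KNOX and vegetative meristem (10), lignified tissue (9), floral MADS-box (10) and pollen (5). Adjusted over the list alone, 3 rose and 1 fell for ABA, 3 rose and 1 fell for auxin. On the same basis, 2 rose and 3 fell for gibberellin, 2 rose and 4 fell for HD-ZIP and bZIP factors, 1 rose and 1 fell each for heat shock proteins and for floral MADS-box genes, 1 rose for sucrose and hexose genes and 1 fell for WRKY factors. Median and mean differed in sign for auxin (-0.03, or -0.04 without genes at 0, and 0.20), kinesins and tubulins (0.15, or 0.20 without genes at 0, and -0.34), pollen markers (-0.09 and 0.13), NAC factors (-0.10 and 0.35), starch (-0.01, or 0.10 without members of another class, and 0.15) and WRKY factors (-0.07 and 0.09), none of them called. The lists of raffinose and polyols (3 tested), proline (4), phospholipid signalling (2) and endosperm storage (3) had too few members for camera, and of these genes pdh2 alone passed limma. Leaf control 2 was low in lists of several kinds: all 12 histone genes lay below leaf control 1, with a median log2 difference of -1.33, as did 17 of 19 kinesin and tubulin genes (-0.64), 21 of 24 expansin and cellulose synthase genes (-0.60), 15 of 18 heat shock genes (-0.58) and 9 of 10 sucrose and hexose genes (-0.39). Of DNA replication genes 3 of 6 lay below (-0.06), and of cyclins and their kinases 6 of 9 (-0.04). Other lists went the other way: 8 of 30 photosynthesis genes lay below (0.21), as did 3 of 10 floral MADS-box genes (0.21) and 7 of 19 aquaporins (0.10). Without leaf control 1, camera called the histones (median log2 change 1.41), the expansins and cellulose synthases (0.76) and the metallothionein list (0.60) as rising. Without leaf control 2 it called the photosynthesis genes (0.23). These settings were run with the preset correlation alone.

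In all, limma called 730 of the 22418 leaf genes tested (3.26%), 527 rising and 203 falling, against 5020 at an unadjusted p under 0.05. Of these calls, 189 were of genes listed at 0 in both libraries of a condition, and without such genes 368 of 22216 passed, 311 rising and 57 falling. With the replicate block it called 351 (230 rising, 121 falling), and the joint fit of all 8 libraries called 1096 (769 rising, 327 falling). The number of calls moved with the library left out. Such a fit takes its spread from the pair of the other condition alone. The log2 difference between libraries had a standard deviation of 0.544 in the leaf controls and 0.307 in the leaf drought pair. A loss of calls without a drought library thus does not tell whether they depend on it.

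**Figure D2:**
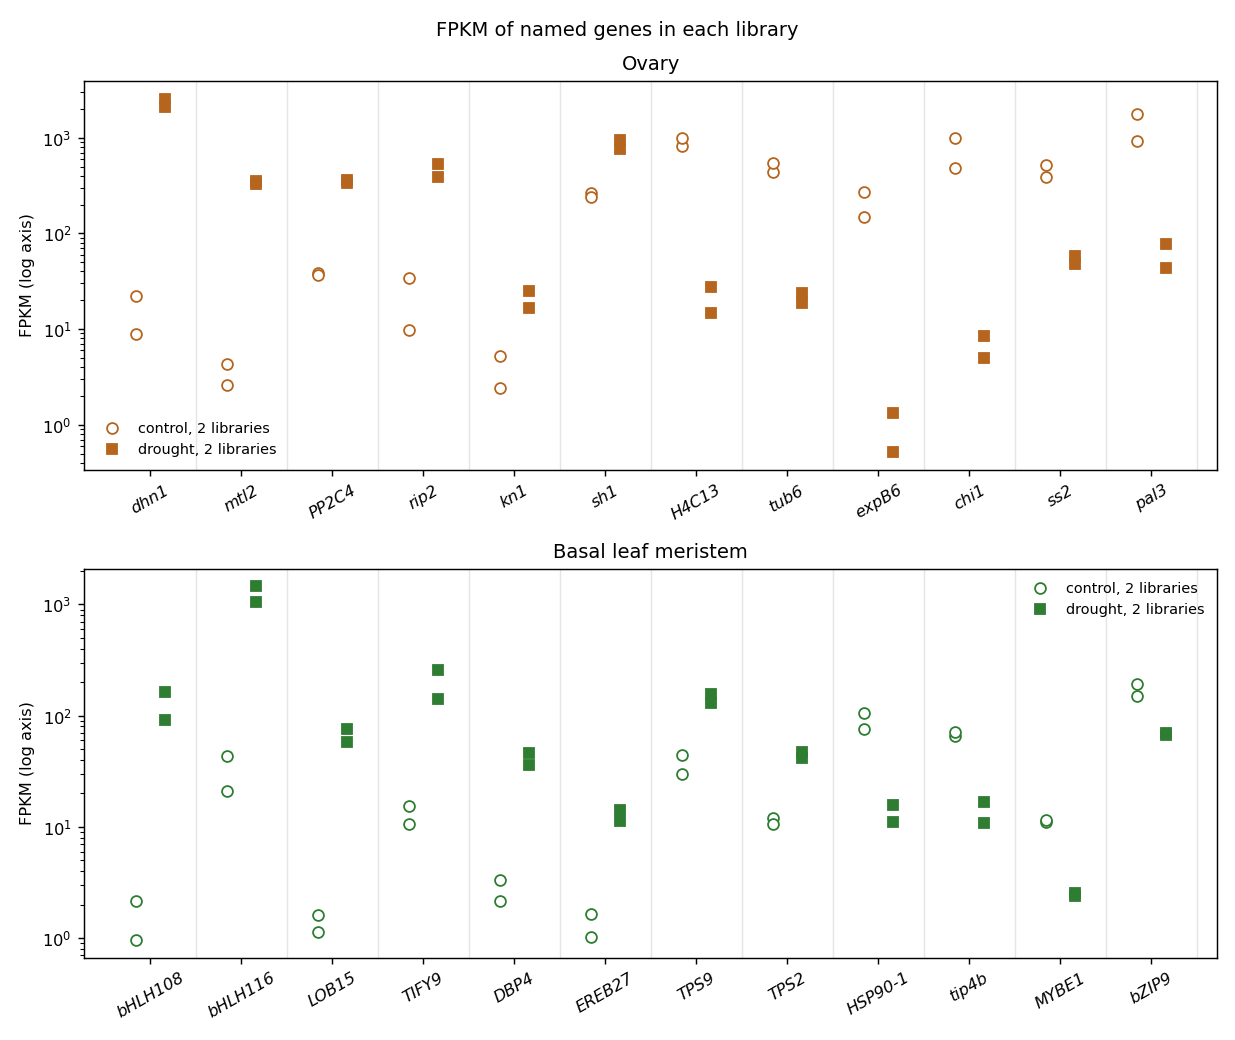
FPKM (log axis) of 12 named genes in the ovary (top) and 12 in the basal leaf meristem (bottom), all above 0 in each library, in the 2 control libraries (open circles) and the 2 drought libraries (filled squares) of each tissue. In every gene drawn, both drought libraries lie on 1 side of both controls, as for dhn1 in the ovary, at 8.81 and 22.3 FPKM in the controls and 2559 and 2094 FPKM under drought.

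The direct comparison of both responses asked which genes respond differently to drought in the ovary and in the leaf meristem. Camera called the lists of histones, kinesins and tubulins, expansins and cellulose synthases, ribosomal proteins and photosynthesis as lower in the ovary response than in the leaf response, and those of abscisic acid, cell death and NAC factors as higher, though none with an estimated correlation (smallest adjusted p = 0.457). It did not call DNA replication genes (camera adjusted p = 0.218) or cyclins and their kinases (0.978), a list in which 4 of the 9 genes tested are kinesin-related. Relative to the leaf response, the log2 change in the ovary was higher by 4.33 ± 0.94 (SE) for dhn1 (limma adjusted p = 0.00808), by 4.38 ± 0.37 for mtl2 (limma adjusted p = 0.000185) and by 6.05 ± 0.40 for sat1 (limma adjusted p = 5.53e-05), which stood at 30.7 and 45.3 FPKM in the leaf controls and 18.8 and 18.2 FPKM in the leaf under drought. It was lower, with differences of -7.48 ± 0.68 for chi1 (limma adjusted p = 0.000272), -6.72 ± 0.28 for hsbp1 (6.22e-06) and -6.45 ± 0.64 for CGTb (0.000372). CER1 differed by -8.33 ± 1.65 (limma adjusted p = 0.00563). It stood at 40.8 FPKM in leaf control 1 and 1.04 FPKM in leaf control 2. The differences for ciszog1, LOL3 (GRMZM2G120079) and the proline-rich protein gene prp2 (GRMZM2G102356) were 4.84, 5.04 and -7.45. In the leaf, prp2 stood at 78.2 and 0.367 FPKM in control 1 and control 2 and at 52.8 and 195 FPKM under drought, and its difference was -4.53 without leaf control 2. The call of prp2 (limma adjusted p = 0.031) ended without ovary control 1 (0.0732), ovary control 2 (0.0857), ovary drought 1 (0.0668), ovary drought 2 (0.0897) or leaf drought 2 (0.0996).

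The largest differences in size were mostly in genes without a symbol that are listed at 0 in a condition. GRMZM2G080466 was listed at 0 in both ovary controls and at 1660 and 1737 FPKM under drought, and stood between 344 and 390 FPKM in the 4 leaf libraries. GRMZM2G016928, GRMZM2G057448, GRMZM2G157621 and GRMZM2G484880 were at 0 in both ovary controls and in both leaf drought libraries, and at 14.4 to 60.1 FPKM and 16.3 to 71.7 FPKM in the ovary under drought and in the leaf controls. In the other direction, GRMZM2G326643, GRMZM2G109821 and GRMZM2G036908 were at 0 in both ovary drought libraries and both leaf controls, and at 20.7 to 60.8 FPKM in the ovary controls and 20.8 to 41.8 FPKM in the leaf under drought. A1, at 0 in the ovary under drought, stood at 134 and 47.9 FPKM in the leaf controls and 191 and 154 FPKM in the leaf under drought. AC187262.4_FG007 fell from 1643 and 1948 to 2.00 and 0.22 FPKM in the ovary and stood at 45.4 and 11.01 FPKM in the leaf controls and 43.0 and 54.4 FPKM in the leaf under drought, a difference of -10.94 ± 0.89 on the log2 scale. Limma adjusted p of these 10 genes lay between 4.77e-07 and 0.000169. Except for AC187262.4_FG007, they can be too small because equal zeros show no spread.

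Of 30 lists tested for the difference, camera called 15. The 11 lists lower in the ovary response were expansins and cellulose synthases (median log2 difference -3.29, camera adjusted p = 8.9e-08), ribosomal proteins (-1.26, 2.31e-05), histones (-4.21, 0.000188), kinesins and tubulins (-2.26, 0.000188) and photosynthesis (-1.06, 0.000447), and also ethylene (-0.76, 0.00787), jasmonate (-1.15, 0.00878), starch (-1.71, 0.0152), auxin (-0.79, 0.0208), heat shock proteins (-1.24, 0.0208) and lignified tissue (-2.75, 0.0468). The 4 lists higher in the ovary response were cell death and autophagy (median log2 difference 0.95, camera adjusted p = 0.000158), NAC factors (0.92, 0.0047), abscisic acid (0.64, 0.0152) and HD-ZIP and bZIP factors (0.45, 0.0317). With an estimated correlation camera called 0 of them, the smallest adjusted p being 0.457 with an estimated correlation. These list tests were not run with a library left out. Nor were they run without members whose symbol names another class of gene, which the heat shock list also holds. In leaf control 2 histones lay at -1.33 relative to leaf control 1, expansins and cellulose synthases at -0.60, jasmonate genes at -0.49 and photosynthesis genes at 0.21. The jasmonate list had a median change of 0.0003 in the ovary and 0.90 in the leaf, so its difference lies mostly in the leaf. Gene by gene, limma called 9678 of the 20252 genes tested in both tables, 4668 with the higher log2 change in the ovary and 5010 with the lower, and 11250 at an unadjusted p under 0.05. Without genes at 0 in a condition it called 9123 of 19718. The number with the higher change in the ovary was 3103 without leaf drought 2. In this comparison levels are not set against each other across tissues, since the tables were made separately: each value is a difference of changes within a table.

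**Figure D3:**
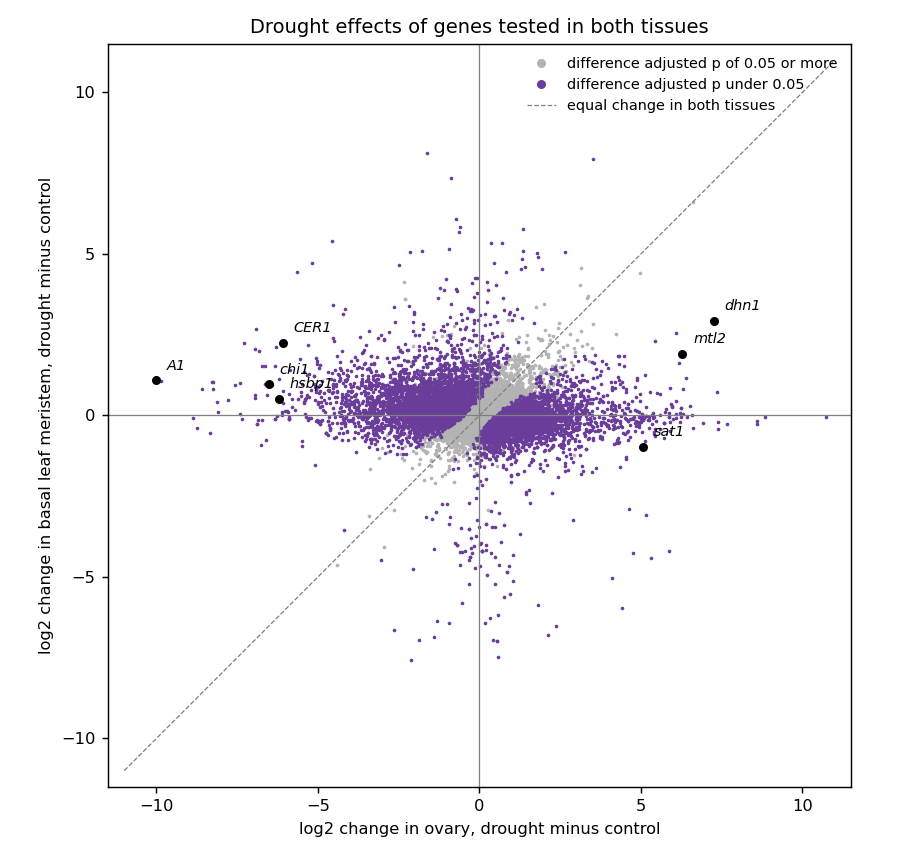
Log2 change with drought in the ovary (horizontal axis) and in the basal leaf meristem (vertical axis), both on the log2(FPKM + 1) scale, for the 20252 genes tested in both tissues. Each point is a gene, purple where limma's adjusted p for the difference was under 0.05 (9678 genes), the dashed line marks equal changes, and the named points include dhn1, at 7.26 in the ovary and 2.93 in the leaf.

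Named genes that rose in both tissues included mtl2 (log2 change 6.28 in the ovary and 1.90 in the leaf), NAC1 (GRMZM2G336533, 3.35 and 3.69), TPS9 (2.95 and 1.95), TPS2 (1.92 and 1.89), TPS7 (1.87 and 1.26), dehydrin3 (GRMZM2G373522, 2.21 and 1.2), the indole-3-glycerol phosphate lyase gene Igl (GRMZM2G046163, 1.91 and 2.38), the chlorophyll breakdown gene SGR1 (GRMZM2G103881, 1.89 and 1.30), TIFY4 (GRMZM2G445634, 2.06 and 1.91), LOB15 (1.31 and 4.83) and bZIP76 (1.47 and 1.49). Genes that fell in both included the thiamine synthesis gene thi2 (GRMZM2G074097, -5.09 and -1.53), the aquaporin tip4a (GRMZM2G103945, -0.97 and -1.72), Dwarf1 (-1.49 and -1.95) and hir2 (GRMZM2G150762), which fell by 0.90 in the ovary and went from 7.89 and 7.88 FPKM in the leaf controls to 0 in both leaf drought libraries. All passed limma in each tissue. With the replicate block the leaf calls of NAC1, TPS9, TPS7, bZIP76 and Dwarf1 ended (limma adjusted p = 0.0875, 0.0817, 0.121, 0.106 and 0.0687). The leaf calls of mtl2, dehydrin3, Igl, SGR1, TIFY4, thi2, tip4a and hir2 were not followed gene by gene with the block or without a control library. Of all 730 leaf calls, 342 were kept with the block. In the leaf fit without genes at 0, limma called no gene of the NAC or metallothionein lists as rising. Over all 20252 genes tested in both, the log2 changes of the tissues had a Pearson correlation of -0.0985 and a Spearman correlation of -0.146 across genes. Of these genes, 139 rose in both tissues, where independent lists would share 104.6 (Fisher's exact test across genes, two-sided p = 0.000175). Another 41 fell in both, where 45.5 would be shared (exact p = 0.482). The genes rising in both were 96, 76, 99 and 77 without ovary control 1, control 2, drought 1 and drought 2 (69.2, 48.9, 53.2 and 39.5 for independent lists). They were 68 without leaf control 2 (45.6) and 57 with the replicate block (45.0). Without leaf control 1 they were fewer than independent lists would share, 252 against 307.7 (exact p = 0.000135). The genes falling in both were also fewer than independent lists would share without leaf control 1. Without any 1 ovary library or leaf control 2 they were near the number of independent lists. Without leaf drought 1 or leaf drought 2 limma called no leaf gene (2526 and 1800 at an unadjusted p under 0.05), so none was shared. Of the 438 genes in this set that rose in the leaf, 109 fell in the ovary, and of the 161 that fell in the leaf, 43 rose in the ovary. Over all 20252 genes, 5727 fell and 4835 rose in the ovary. The opposite changes were not tested against independent lists. Without genes at 0 in a condition, 88 rose in both (62.7 for independent lists; exact p = 0.000451) and 11 fell in both (11.7; exact p = 1). Genes are not independent replicates, so these p-values describe these lists of genes.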

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

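The difference between the drought responses of ovary and leaf was tested directly, and each gene and list in the next 3 paragraphs passed that test. Among the tests weighed below, those of missing estimates, of both silk explanations and of shares of dividing tissue were chosen only after the result was seen, as were the genes not at 0 named for the tissue difference.

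Limma called 9678 genes whose response differed. The list medians of the ovary change minus the leaf change were -4.21 for histones, -3.29 for expansins and cellulose synthases, -2.75 for lignified tissue, -2.26 for kinesins and tubulins, -1.71 for starch, -1.26 for ribosomal proteins, -1.24 for heat shock proteins, -1.15 for jasmonate, -1.06 for photosynthesis, -0.79 for auxin, -0.76 for ethylene, 0.95 for cell death and autophagy, 0.92 for NAC factors, 0.64 for abscisic acid and 0.45 for HD-ZIP and bZIP factors, on the log2 scale. None of these lists was called with an estimated correlation (smallest camera adjusted p = 0.457 with an estimated correlation). The list tests were not run with a library left out.

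The largest fitted log2 differences by the naming rule were 10.80 for GRMZM2G080466, 10.40 for GRMZM2G016928, 10.06 for GRMZM2G057448, 9.71 for GRMZM2G157621 and 9.16 for GRMZM2G484880, and -11.09 for A1, -10.94 for AC187262.4_FG007, -10.11 for GRMZM2G326643, -9.98 for GRMZM2G109821 and -9.90 for GRMZM2G036908. All but AC187262.4_FG007 are listed at 0 in a condition, where the fitted value depends on the pseudocount and is no bound. Among genes not at 0 and with a symbol they were 6.05 for sat1, 5.04 for LOL3, 4.84 for ciszog1, 4.38 for mtl2, 4.33 for dhn1, -8.33 for CER1, -7.48 for chi1, -7.45 for prp2, -6.72 for hsbp1 and -6.45 for CGTb. The difference for prp2 was -4.53 without leaf control 2. The call of prp2 (limma adjusted p = 0.031) ended without ovary control 1 (0.0732), ovary control 2 (0.0857), ovary drought 1 (0.0668), ovary drought 2 (0.0897) or leaf drought 2 (0.0996).

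Of the 122 genes named in the text and tested in both tissues, 102 differed between them. Many were named because of a large change or difference, so the choice largely sets this share. Of all 20252 genes tested in both tissues, 9678 differed. Those with the higher change in the ovary and not at 0 had log2 differences of NAC1 (GRMZM2G347043 alone of its 3 IDs) 4.30, AUX10 4.11, gols2 3.85, rip2 3.82, HSP90-1 3.17, MYBE1 3.03, PP2C11 2.90, sat2 2.85, CKX4 2.80, Atg7 2.79, CKX5 2.74, lls1 2.62, lg2 2.61, PP2C4 2.60, RR9 2.52, PP2C16 2.49, tip4b 2.18, hk2 2.02, cat1 1.85, sh1 1.82, bZIP9 1.797 and dehydrin3 1.01. Those with the lower change in the ovary had LTP3 -6.25, expB4 -5.97, sm1 -5.92, expB6 -5.85, tub6 -5.58, H4C13 -5.43, H3C2 -5.38, lox1 -5.30, his2a1 -4.91, lhcb6 -4.73, expa1 -4.54, tub4 -4.12, pcna2 -3.92, TIFY9 -3.88, tub5 -3.76, BM1 -3.73, rbcS -3.58, thi2 -3.56, LOB15 -3.52, TIFY28 -3.30, GBSSIIa -3.12, pip2c -3.09, AUX17 -2.90, MCM6 -2.83, invertase1 -2.83, ss2 -2.69, rbcs1 -2.67, frk2 -2.59, RPS27A -2.17, rps28 -1.93, MADS18 -1.85, bt2 -1.57, CKX6 -1.39, pcna1 -1.33, Pep1 -1.26 and D8 -1.20. Of genes at 0 in a condition, with fitted values that depend on the pseudocount, the differences were Atg8b 7.14, HMT-3 7.01, hppd1 6.55, RPL10 5.63, rld1 5.39, bZIP83 5.17, arpp1a 5.08, TPS3 5.07, pdh2 3.99 and hir2 2.25, and eif5a -8.80, c2 -8.55, sm2 -8.25, abp1 -8.23, expA3 -7.86, grf2 -7.82, cesa2 -7.57, lhcb3 -7.49, whp1 -6.47, EREB27 -5.38, Ots1c -4.99, AGA1 -4.40, EREB171 -3.73 and lac4 -2.75.

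Genes listed at exactly 0 in both libraries of a condition, at whatever level in the other, make up 637 of the ovary calls and 189 of the leaf calls. Expression near 0 in that condition would leave small values too, but among genes at 10 FPKM or more in the other condition exact zeros in both libraries outnumbered values under 0.5 FPKM by 4.46 times in the ovary (366 against 82) and by 44 times in the leaf (132 against 3), which argues against it as the whole explanation. Estimates missing for particular genes and conditions in the authors' processing are a candidate explanation: 13 genes were at 0 in a condition of both tissues, where independent lists of 211 and 101 among 10780 genes would share 1.98 (Fisher's exact test across genes, two-sided p = 7.66e-08). A silencing of some of these genes by drought stays open and was not tested.

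More than 50% of the tested ovary genes changed (12618 of 23770), or 8595, 7165, 7064 and 5800 without control 1, control 2, drought 1 and drought 2. A difference in scale or distribution between libraries is argued against as the cause of this number. Limma called 12863 genes after quantile normalization (6657 rising and 6206 falling) and 12740 after upper quartile scaling. Dilution of ovary RNA by leaf-like tissue is argued against as the whole cause, by genes chosen on their level in each table. Of 768 called genes at a mean of at least 5 FPKM in the ovary and under 1 FPKM or not listed in leaf, 41.9% rose. Dilution beside other changes could leave such a share, so as a contributor it stays open. A smaller share of silk in the drought samples stays open as a cause of the rising calls: their log2 changes had a standard deviation 4.26 times the median standard error, which decides nothing, since genes differ in how much of their RNA would come from silk. As a cause of falling calls it stays open too: 6 silk flavone genes, chosen because they fell, had a median log2 change of -6.02, with p1, c2, whp1 and sm2 listed at 0 under drought and chi1 and sm1 at 3.43 to 8.45 FPKM, but 5 of the 6 are also measured in the leaf. A response of the ovary itself, or a difference in developmental stage between the conditions, stays open and was not tested. The series description names cob for the control samples only, and the share of cob tissue is not known. A difference in cob share would run along the same contrast as drought, so these data cannot tell it apart.

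The number of leaf calls moves with the library left out, from 0 without leaf drought 1 or leaf drought 2 (limma; 2526 and 1800 at an unadjusted p under 0.05) to 375 without leaf control 2 and 1988 without leaf control 1. A scale difference of leaf control 2 is argued against, since after upper quartile scaling the counts without control 1 and without control 2 still differed 4.90 times (1942 against 396). Different shares of dividing tissue in the controls may contribute: 32 of 37 histone, replication, kinesin and tubulin genes were lower in control 2, with a median log2 difference of -0.74, against -0.17 to 0.05 in the middle 90% of 10000 random sets. It stays open, because the histones (-1.33) and the kinesins and tubulins (-0.64) lay below their random sets while the replication genes (-0.06) lay at percentile 52.7, heat shock (-0.58) and jasmonate genes (-0.49) were low as well, and the design has no measure of tissue share. Differences between plants stay open as well, untested. In a fit without 1 library the spread also comes from the pair of the other condition alone. The log2 difference had a standard deviation of 0.544 between the leaf controls and 0.307 between the leaf drought libraries.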

How the results depend on the processing

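None of the called lists, and none of the 115 ovary and 31 leaf named genes called, changed direction under the alternatives run for them. The balance of ovary calls did: 5614 rising and 7004 falling became 6657 and 6206 after quantile normalization. The overlap of rising genes, above that of independent lists (139 against 104.6), was below it without leaf control 1 (252 against 307.7, and 78 falling). Some lists without a call changed the sign of their median, such as ovary trehalose (0.85, and -0.17 without genes at 0) and leaf histones (0.61, and -0.10 without leaf control 2), and camera's direction for ovary DREB and ERF factors turned after quantile normalization. The fits without genes at 0, the lists without members of another class, the crossed block, and the overlap with a library left out or with the block were chosen after seeing the data. In the ovary, counts under the other settings lay between 9697 and 13145, and at a 2-fold minimum limma called 7922 genes, 3254 rising and 4668 falling, by construction fewer. Leaving out 1 ovary library gave 5800 to 8595 genes (2257 to 3791 rising, 3543 to 4804 falling), the lowest without drought 2 and the highest without control 1. In the leaf the replicate block gave 351 genes (230 rising, 121 falling) and crossed replicate numbers 611; deviations of equally numbered libraries correlated across genes at 0.112 in the ovary and -0.175 in the leaf, and the labels name no shared batch. Without genes at 0 in both libraries of a condition 368 leaf genes were called (311 rising, 57 falling), all of them among the 730, and the joint fit of all 8 libraries called 1096, 327 of them falling; the other leaf settings gave 611 to 793. Leaving out 1 leaf library gave 0 to 1988 genes (0 to 1509 rising, 0 to 479 falling), with limma calling 0 without drought 1 or drought 2 (2526 and 1800 at an unadjusted p under 0.05); the cause was not tested. With an estimated correlation camera called 0 lists in the ovary and 0 in the leaf, against 14 and 4; the smallest adjusted p were 0.561 and 0.725 with an estimated correlation, and in simulated data it missed the moved list too. Leaving out 1 library gave 13 to 15 ovary lists and 4 to 7 leaf lists. Lists gained under an alternative in the ovary were HD-ZIP and bZIP factors at 5 FPKM (camera adjusted p = 0.0223) and aquaporins with the block (0.0478) and without genes at 0 (0.03). In the leaf they were trehalose at 5 FPKM (0.0395), without a filter (0.0457) and without genes at 0 (0.0463), and cell death, falling, without a filter (0.0457). Leaf trehalose was also gained without members of another class. With a library left out, camera gained ovary aquaporins without control 1 and leaf trehalose without drought 2. It likewise gained leaf histones, expansins and metallothioneins without leaf control 1 and photosynthesis without leaf control 2. Of the 115 named ovary genes called, 6, 14, 11 and 14 lost the call without control 1, control 2, drought 1 and drought 2, 1 at a pseudocount of 0.1 FPKM and 0 with upper quartile scaling or the block. Of 31 in the leaf, 2, 12, 31 and 31 lost it without control 1, control 2, drought 1 and drought 2, 12 with the block, 2 at a pseudocount of 0.1 FPKM and 0 with upper quartile scaling. The difference between tissues held 6689 to 9680 genes with 1 library left out, those higher in the ovary 3103 to 4743, and prp2 lost its call also at a pseudocount of 0.1 FPKM (limma adjusted p = 0.0503) and with the block (0.0539). Only the 20 genes named for the tissue difference were followed under these settings. The other genes listed as differing were not, among them lox1 (limma adjusted p = 0.0419 for the difference). Genes falling in both tissues were 22 at a mean of 5 FPKM, where fewer genes are tested, and without genes at 0 the overlap was 99 genes, 88 rising and 11 falling; the other pseudocount, filter and 2-fold settings gave 136 to 164 genes. The overlap of 180 genes became 86 with the block, 99 to 129 without 1 ovary library, 330 without leaf control 1, 99 without leaf control 2, and 0 without leaf drought 1 or leaf drought 2, where limma called 0 leaf genes (2526 and 1800 at an unadjusted p under 0.05). Read depth is unknown, so what it limits cannot be given.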

Other observations

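The lists and genes here were chosen after seeing the data. In the ovary, of 22 genes of cytokinin breakdown and signalling 10 rose, 2 fell and 10 did not pass limma, also when adjusted over the list alone, without a call by camera (adjusted p = 0.0631). The cytokinin oxidase genes CKX4 (GRMZM5G817173) and CKX5 (GRMZM2G325612) rose by 3.76 and 3.00 on the log2 scale, the response regulator RR9 (GRMZM2G060485) by 2.31 and the receptor kinase hk2 (GRMZM2G471529) by 1.84, while CKX6 (GRMZM2G404443) fell by 1.95. Of 16 HAK potassium transporters 8 rose and 1 fell, of 15 protein disulfide isomerases 8 fell, of 9 cell number regulators 1 rose and 7 fell, and of 6 cellulases 5 fell. Of 41 MYB factors 13 rose and 13 fell, of 28 bHLH factors 9 rose and 7 fell, of 23 glutathione S-transferases 5 rose and 7 fell, of 27 GRF, WOX and TCP factors 7 rose and 10 fell, and of 7 benzoxazinoid genes 1 rose and 3 fell. Camera called 0 of these 10 lists, with adjusted p between 0.0631 and 0.985. In the leaf, camera called 0 of the 9 lists tested; 2 bHLH factors rose and 1 fell, 2 MYB factors rose and 2 fell, and 1 GRF, WOX or TCP factor rose. In the fit without genes at 0, no leaf MYB, GRF, WOX or TCP factor rose.

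Several genes of flavonoid synthesis fell in the ovary; they were picked because they fell, and no list of them was tested. Besides A1, c2, chi1, sm2, CGTb and pal3, the chalcone synthase gene whp1 (GRMZM2G151227; 33.1 and 59.8 FPKM in the controls) and the MYB regulator p1 (GRMZM2G084799; 10.4 and 20.5 FPKM) were listed at 0 in both drought libraries, and sm1 (GRMZM2G031311) fell from 156 and 231 to 3.43 and 3.74 FPKM. Limma adjusted p of whp1, p1 and sm1 were 0.000119, 0.000371 and 5.89e-05.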
